A study of Drosophila melanogaster with 2 samples.

How the data were processed

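Chromatin from whole embryos aged 0 to 24 hours of flies that express an E2f1-eGFP fusion was precipitated with an anti-GFP antibody and sequenced, in 2 biological replicates of 1 group, per the labels. The fragments were sonicated to a size range of 200 to 800 bp and the files use the dm6 build, per the labels. The labels name another experiment as a possible control; its data are not used here. The aligner, the peak caller and their versions are not given in the sources used here. The files hold no read counts, so the depth of each library and the precision it gives are unknown, and intervals and p-values are over regions or genes, which are not independent replicates and cover counting error only.

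For each replicate the authors deposited a ranked list of candidate regions with an IDR (the irreproducible discovery rate of a region between 2 inputs) and a thresholded set. For both replicates together they deposited 2 ranked lists and 2 thresholded sets, a conservative one and a larger one. Every region of the 4 thresholded sets had a global IDR of 0.01 or lower in its ranked list. The conservative set came from the ranked list whose inputs are replicate 1 and replicate 2, as matching the input coordinates to each replicate's own list showed; 54.8% of its first inputs were in the list of replicate 1 and 53.4% of its second inputs in that of replicate 2. It is called the reproducible set. The inputs of each replicate's own list are not named in the files, so whether a replicate's set tells how regions recur within that library is unknown. Peak heights are scores in the authors' files, with no stated rescaling between libraries. They were used to rank and describe regions within a set and for a correlation over shared regions. The deposited -log10 values are those of a q-like value and of the global IDR, with a ceiling of 5 for the latter.

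Summits were taken from the authors' files and written 1-based. Genes and TSSs came from the Ensembl annotation BDGP6.54, release 115, and sequence from the RefSeq assembly of the same build; all regions fell within its chromosome lengths. A gene was called bound if a summit lay within 500 bp of any of its TSSs, so 1 summit can count for both genes of a divergent pair. Features followed the priority promoter, 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic, on chromosomes 2L, 2R, 3L, 3R, 4 and X. Where 1 of the 4 counts of an odds ratio was 0, a constant under 1 was added to each, so such odds ratios (chemoreceptor, testis and rRNA genes) depend on it, while the tests do not. The tests, all two-sided, were exact binomial tests for features, Fisher's exact tests for arms, gene types with at least 50 genes and gene lists, and exact McNemar tests for motifs in windows of 50 bp each side of the summit against windows centred 500 bp to a random side, each with Benjamini-Hochberg adjustment within its family and a threshold of 0.05. Odds ratios with a count of 0 had a constant added to each cell. The side of each control window was drawn anew for each set of summits, so control counts can also move with the draw. Random placement of regions was drawn 100 times. All results were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

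The design, the alternatives, the motifs and the 15 gene lists were fixed before the data were examined. The lists were E2F, Rb and dREAM components, DNA replication and nucleotide supply, cyclins, Cdks and their regulators, mitosis and chromosome segregation, DNA repair and damage response, chromatin assembly and histone supply, apoptosis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, muscle structure, neuronal function, embryonic patterning factors, testis and sperm, and chemoreceptors. The lists held 628 genes in all, 4 of them matched through an older symbol. Named genes followed a fixed rule: E2f1, Dp, E2f2, Rbf, PCNA, RnrL, RnrS, Orc1 and CycE whether bound or not; the gene with the nearest TSS for each of the 10 highest regions; for each list past the test its 3 highest bound members and, where 4 or fewer members were not bound, those, otherwise the first 2 not bound in alphabetical order; and for each other list its 2 highest bound members. Genes named in the other observations outside this rule were chosen after their values were seen.

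The alternatives were the larger set over both replicates, each replicate's set alone, a global IDR of 0.01, promoter distances of 200 and 1000 bp, other rules for a shared region (reciprocal overlap of 50%, summits within 100 bp), logistic regression with promoter GC content, CpG count and TSS number, a background of the 10383 genes with a candidate region at the promoter, 1 gene per cluster of TSSs (11708 clusters), binding by overlap of the whole region, motif windows of 25 and 100 bp each side, control windows 200 bp away or dinucleotide-shuffled, and promoter or other summits only. An IDR of 0.001, the removal of regions matched to the same input region as a higher neighbour, and a q-like value of 0.05 or lower were added after the data had been seen.

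The statistics were tested on simulated data. With an odds ratio of 5 written into 1 list over 13945 genes, 100 simulations recovered the replication list in 94% of cases, the ribosomal protein list in 100% and the chromatin assembly list, which has 14 members, in 46%. In these simulations other lists were called in at most 0.5% of tests, and in 0.0667% with no list changed. A planted share of 70% of regions was recovered as 70%. The E2F consensus written into 3% more of 4439 windows was recovered in each of 20 simulations. There the summit and control windows shared 1 base composition, while the real ones had a mean GC content of 33.8% and 43.4%. The simulation therefore cannot tell whether an excess would be found under that difference. Regions on unplaced scaffolds, of which replicate 2 had 14 and the larger set 4, were left out of the tests on features, genes and motifs.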

Results

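The series measured where the transcription factor E2f1 sits on the genome of whole Drosophila melanogaster embryos aged 0 to 24 hours. E2f1 is the activator member of the fly E2F family, which with its partner Dp drives genes needed for DNA synthesis. The flies carried a transgene that makes E2f1 fused to enhanced green fluorescent protein (eGFP), and chromatin sonicated to 200 to 800 bp was precipitated with an antibody against GFP and sequenced (ChIP-seq). There was 1 group with 2 biological replicates, and no second condition or stage, so the comparisons are between the replicates and between bound and unbound parts of the genome. The files give regions, not reads, so the read depth of each library is unknown. Coordinates are in the dm6 build.

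At the authors' threshold, replicate 1 had 3779 regions and replicate 2 had 3280. The set reproducible between the replicates had 4439 regions with a median width of 344 bp. The results below rest on this set unless another is named. A region in it need not be in each replicate's own set. Of the 4439 regions, 68.8% overlapped a region in the set of replicate 1 and 67.3% one in that of replicate 2. Only 55.3% (2454 of 4439) overlapped a region in both. A q-like value above 0.05 was found for 754 of the 4439. Strong regions were shared and weak regions were often not. Of the replicate 1 regions 67.5% (2551 of 3779, exact 95% interval 66.0 to 69.0) overlapped a replicate 2 region by at least 1 bp, and of the replicate 2 regions 74.9% (2458 of 3280, interval 73.4 to 76.4) overlapped a replicate 1 region. Random placement of the other set on the same chromosomes gave a mean of 1.42% and 1.64%, and no more than 2.12% and 2.29% in 100 placements. In the fifth of regions with the highest peaks 98.1% of replicate 1 and 99.2% of replicate 2 were shared, and in the fifth with the lowest peaks 38.6% and 41.01%. Over 2419 region pairs the peak heights correlated with a Pearson r of 0.855 on the log2 scale and a Spearman coefficient of 0.817, and the summits lay a median of 20 bp apart. These correlations are across regions, which are not independent replicates.

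**Figure D1:**
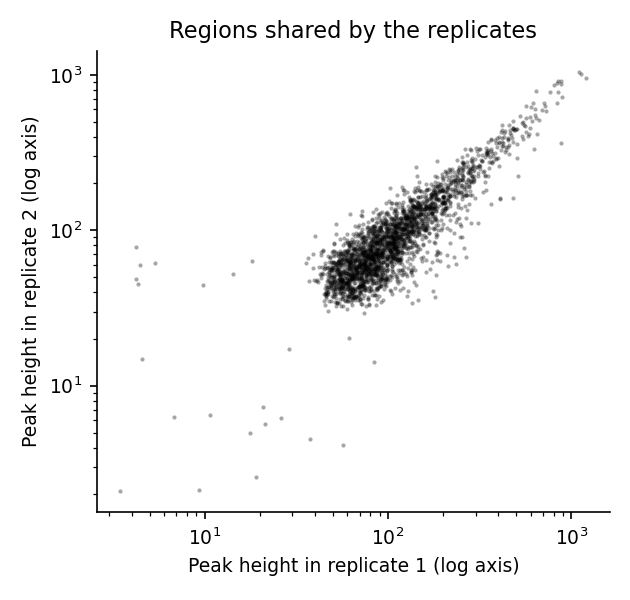
Peak height (the authors' score) in replicate 1 against replicate 2, both on log axes, with 1 point for each of the 2419 pairs of overlapping regions. Most points follow a single band, and a few pairs with a height under 20 in 1 or both replicates lie off it; the Pearson r over all pairs is 0.855 on the log2 scale.

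E2f1-eGFP summits were enriched at promoters and nearly missing from coding sequence, though in the reproducible set most lay more than 500 bp from a TSS. Within 500 bp of a transcription start site (TSS) lay 46.02% of summits (2043 of 4439, exact 95% interval 44.5 to 47.5), against 13.6% of the genome, a ratio of 3.396. Coding exons held 0.428% of summits and 13.7% of the genome (adjusted p = 1.58e-247, exact binomial test, two-sided; 0.217% to 0.775% of summits in other settings), and 3' UTRs held 0.834% and 4.43% (adjusted p = 5.44e-45), with 0.551% in replicate 2 alone. Intergenic sequence held 14.3% of summits and 27.2% of the genome (exact adjusted p = 5.94e-95). Promoter shares were 50.97% in replicate 1 and 46.9% in replicate 2.

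Introns held 37.0% of summits and 39.5% of the genome (exact adjusted p = 0.00120). With a promoter distance of 200 bp the intron share was 43.05%, above that of the genome under the same rule (exact adjusted p = 0.0447). The 5' UTR share of 0.405% lay below the genome's 0.779% (exact adjusted p = 0.00317), but not in replicate 1 taken alone (0.529%, adjusted p = 0.110). Other exons did not pass the test (1.04% against 0.820%, exact adjusted p = 0.113). Of the promoter summits 79.7% lay at or upstream of the nearest TSS, with a median position of -103 bp and quartiles of -190 and -22 bp.

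**Figure D2:**
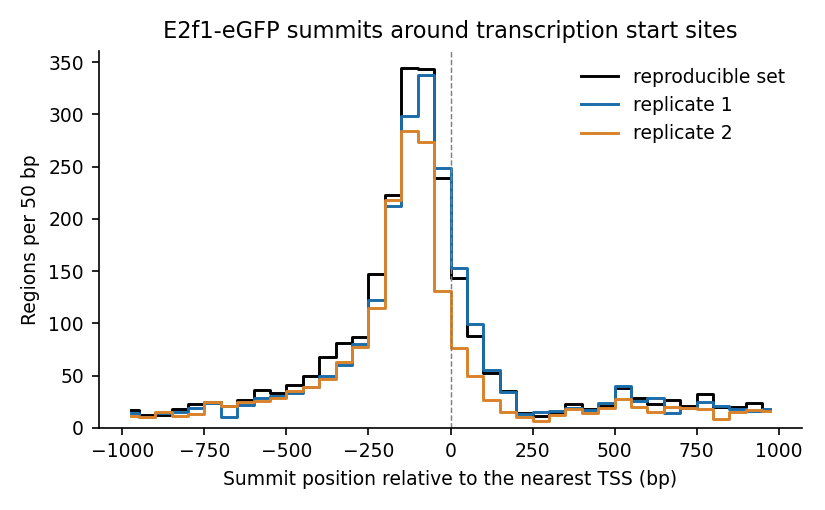
Number of regions per 50 bp (vertical axis) by the position of the summit relative to the nearest TSS in bp (horizontal axis, negative upstream) for the reproducible set and the set of each replicate. All 3 curves peak upstream of the TSS, and the median promoter summit of the reproducible set lies at -103 bp.

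Of the 10 highest regions, with heights from 1601 to 2185, 9 had their summit at a promoter. The highest (chromosome 2L, 6612532 to 6612885, height 2185) lay in an intron, 1019 bp downstream of the nearest TSS, that of CG11050. It was followed by the promoters of CG14100 (chromosome 3L, 19590450 to 19590788, height 2140) and of Ugalt (chromosome X, 2703718 to 2704052, height 2136), which encodes a UDP-galactose transporter. Then came CG7601, mRpL41 (a mitochondrial ribosomal protein), ph-p (a Polycomb group protein), Tcs5, Art3 (a protein arginine methyltransferase), PNPase (polynucleotide phosphorylase) and CenG1A. An E2F consensus site, TTSSCGC with S for C or G, lay within the region in 2 of the 10, those of ph-p and Tcs5, at 124 and 156 bp from the summit. Of control windows with 100 bp each side, which are narrower than these regions, 11.2% held the consensus.

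A summit lay within 500 bp of a TSS of 2460 of 13945 protein-coding genes (17.6%), which are called bound here; 2209 genes were bound in replicate 1, 1930 in replicate 2 and 1587 in both. Genes of DNA replication and nucleotide supply were bound far more often than other genes: 24 of 41 (58.5%, exact 95% interval 42.1 to 73.7) against 17.5% (odds ratio 6.65, adjusted p = 2.52e-08, Fisher's exact test, two-sided, Benjamini-Hochberg over 15 lists). The odds ratio was 11.6 in replicate 1 (exact adjusted p = 3.55e-13) and 5.98 in replicate 2 (adjusted p = 4.39e-07). The highest were PolA1, the catalytic subunit of DNA polymerase alpha (height 736), RnrS, the small subunit of ribonucleotide reductase (559), and dpa, the Mcm4 subunit of the replicative helicase (527). Orc1, the largest subunit of the origin recognition complex, had a height of 421, and PCNA, the sliding clamp of the polymerases, 170.

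The Orc1 region (chromosome 2R, 7525612 to 7525842) had its summit 6 bp upstream of the TSS, with the E2F site TTGGCGC at 7525707 to 7525713. The dpa region (chromosome 2R, 7499807 to 7500152) had the same site from 7499957, at 17 bp from the summit. The PolA1 region (chromosome 3R, 21671657 to 21671937) had TTCCCGC at 62 bp, and the RnrS region (chromosome 2R, 11985392 to 11985705) TTGCCGC at 119 bp. The PCNA region (chromosome 2R, 20262735 to 20263078) had its summit 24 bp upstream of the TSS and held no match to the consensus. Among the 17 members not bound were RnrL, the large subunit of ribonucleotide reductase, Fen1, a flap endonuclease, and Gnf1, a subunit of the clamp loader. RnrL was bound in replicate 1 but not in replicate 2. The list had 28 bound members in replicate 1 and 20 in replicate 2.

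Repair and chromatin assembly genes were also bound more often than other genes. In the list of DNA repair and damage response 13 of 26 genes were bound (50%, odds ratio 4.69, exact adjusted p = 6.11e-04), the highest being mei-41, the fly ATR kinase (height 439), Irbp, a subunit of the Ku complex (402), and spel1, a mismatch repair protein (269). Blm, a RecQ helicase, and Brca2, a recombination mediator, were not bound, although Brca2 was in replicate 1. The summits at mei-41 and Irbp lay closer to the TSS of a neighbouring gene, TH1 and mgr, and that at His2Av in the next list closer to the TSS of ball. In the list of chromatin assembly and histone supply 7 of 14 genes were bound (50%, odds ratio 4.68, exact adjusted p = 0.0142). They were led by the gene of the large subunit of chromatin assembly factor 1 (FBgn0030054, height 797), with TTGCCGC at 26 bp from the summit, dre4, a subunit of the FACT histone chaperone (254), and His2Av, a histone H2A variant (216). The histone chaperone asf1, bound in replicate 1 alone, and the embryonic linker histone BigH1 were not bound. At an IDR (irreproducible discovery rate) of 0.001 both lists missed the threshold (odds ratios 2.68 and 4.05, exact adjusted p = 0.0773 and 0.0604). The chromatin assembly list also missed it in replicate 2 alone (odds ratio 3.46, exact adjusted p = 0.0857; 9.60 with adjusted p = 1.73e-04 in replicate 1) and against genes with a candidate region (odds ratio 3.23, adjusted p = 0.0619).

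Genes of cytosolic ribosomal proteins and of glycolysis were also bound more often than other genes, in the reproducible set at percentages near the 58.5% of replication genes; the difference from replication genes was not tested, and in replicate 1 these stood at 68.3%. Of the cytosolic ribosomal protein genes 54 of 92 were bound (58.7%, exact 95% interval 47.9 to 68.9, odds ratio 6.76, adjusted p = 1.64e-17), led by RpL7 (height 455), RpS27 (385) and RpL32 (355). RpL10 and RpL10Aa were among the 38 not bound. The counts were 53 in replicate 1 (57.6%) and 47 in replicate 2 (51.1%). A symbol pattern gave the ribosomal protein list. It therefore also held genes such as RpL22-like and RpL24-like, which were not bound, and RpLP0-like, which was. Of the glycolysis genes 7 of 12 were bound (58.3%, odds ratio 6.55, exact adjusted p = 0.00546), led by Gapdh2 (height 765), Eno (412) and Ldh (294), while Ald1 and Gapdh1 were among the 5 not bound. The glycolysis list missed the threshold with a promoter distance of 200 bp (odds ratio 3.55, exact adjusted p = 0.0955). It also missed it with promoter GC content, CpG count and TSS number as covariates (odds ratio 3.42, adjusted p = 0.10, logistic regression, n = 13945 genes). Oxidative phosphorylation genes did not pass the test, with 14 of 80 bound (17.5%, odds ratio 0.990, exact adjusted p = 1), with the complex I subunits ND-ASHI (height 389) and ND-MWFE (260) highest. Both of these summits lay closer to the TSS of a neighbour, Fum1 and TppII. The oxidative phosphorylation list was drawn by a symbol pattern, so it also held genes such as ATPsynbetaL and ATPsynepsilonL, which were not bound.

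Chemoreceptor genes, which act in sensory neurons, and testis genes had no bound member. None of 179 chemoreceptor genes was bound (exact 95% upper limit 2.04%, odds ratio 0.0128, adjusted p = 8.06e-15; odds ratio 0.0646 with a promoter distance of 1000 bp), the receptors Gr10a and Gr10b among them. None of 22 testis and sperm genes was bound either (upper limit 15.4%, exact adjusted p = 0.0490), aly, a regulator of the spermatocyte programme, and bol, an RNA-binding protein of meiosis, among them. The testis call was lost in most other settings, including each replicate alone (exact adjusted p = 0.117 in replicate 2 and 0.0570 in replicate 1).

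The remaining lists did not pass the test. Embryonic patterning factors had 2 of 35 bound (5.71%, odds ratio 0.282, exact adjusted p = 0.138): tin, a homeobox gene of the heart (height 446), and Antp, a Hox gene (70.6), which was in neither replicate's own set. Mitosis and chromosome segregation had 11 of 39 (28.2%, odds ratio 1.84, exact adjusted p = 0.153), led by SMC2, a condensin subunit (249), and tum (208). Cyclins, Cdks and their regulators had 5 of 23 (21.7%, exact adjusted p = 0.877), with Cdk2 at 339 and Cdk1 at 112, the latter closer to the TSS of mRpS7. Apoptosis genes had 3 of 15 (20%, exact adjusted p = 0.945), including hid (178) and the caspase gene Drice (107). Neuronal genes had 3 of 20 (15%, exact adjusted p = 1), including elav (687) and Nrx-1 (174), and muscle genes 2 of 18 (11.1%, adjusted p = 0.945), the titin-like sls (266) and the actin gene Act87E (84.6), which was bound in replicate 1 but not in replicate 2. With the larger set over both replicates, mitosis genes passed the test (odds ratio 2.84, exact adjusted p = 0.00437), as did patterning factors (odds ratio 0.119, adjusted p = 0.0168); in replicate 1 alone the patterning odds ratio was 0.156 (adjusted p = 0.0570) and in replicate 2 alone 0.183 (adjusted p = 0.134).

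**Figure D3:**
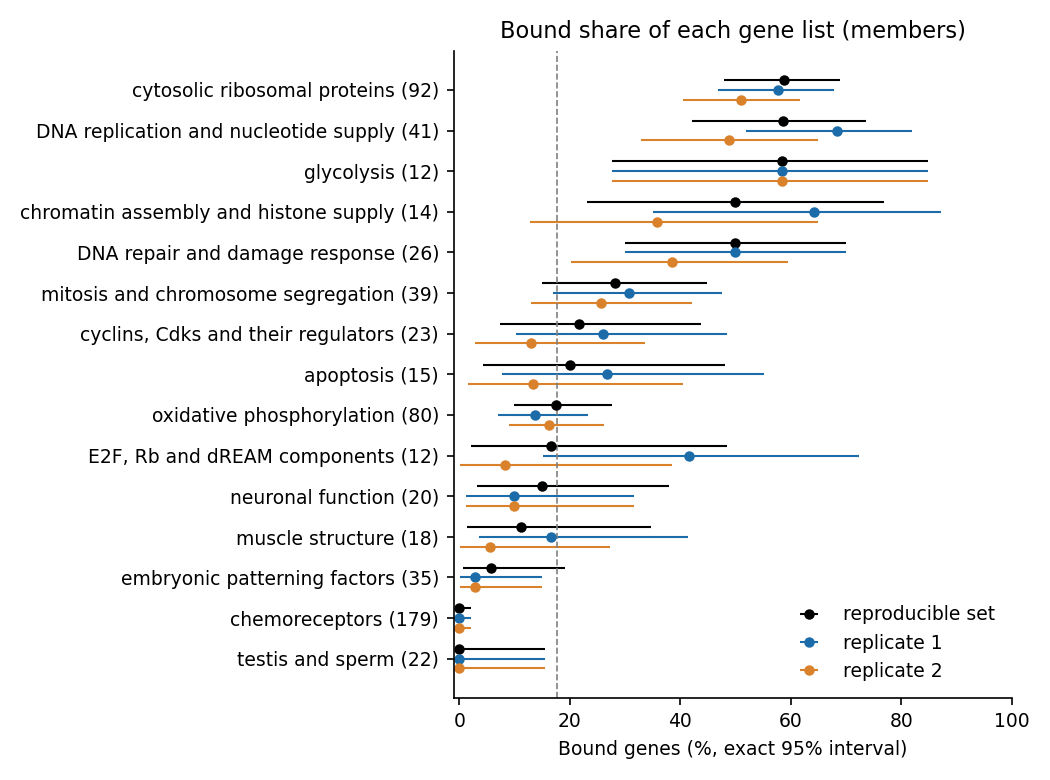
Percent of the genes of each list that were bound (horizontal axis, with exact 95% intervals) in the reproducible set and in each replicate, with the number of members in brackets and the 17.6% of all coding genes as a dashed line. In the reproducible set ribosomal protein, replication and glycolysis genes lie near 58%, and chemoreceptor and testis genes at 0; replication genes lie at 68.3% in replicate 1 and 48.8% in replicate 2.

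The E2F system itself was bound in part. Of 12 genes of E2F, Rb and dREAM components, 2 were bound (16.7%, odds ratio 0.934, exact adjusted p = 1), Dp and mip130, a dREAM subunit (height 89.96). The mip130 promoter was bound in replicate 1 but not in replicate 2, and its summit lay closer to the TSS of Edem1. The Dp gene (chromosome 2R, 13222433 to 13228202) had 3 promoter regions, with heights of 403, 443 and 228. Those of height 403 and 443 held the E2F site TTGGCGC, at 31 and 84 bp from the summit. The region of height 228 held no match. The promoters of E2f1, of E2f2, the repressor E2F, and of Rbf, the fly retinoblastoma protein, were not bound. In replicate 1 alone 5 of the 12 were bound (odds ratio 3.80, exact adjusted p = 0.0557), E2f1 and Rbf among them, and in replicate 2 alone 1. Inside the E2f1 gene (chromosome 3R, 21620304 to 21660871) lay 4 regions, all intronic, with heights of 305, 86.2, 146 and 151. CycE, which encodes cyclin E, had no summit within 500 bp of its TSSs, and was bound in replicate 2 alone, but 1 region of the reproducible set (chromosome 2L, 15747411 to 15747677, height 341) inside the gene held the E2F site TTCCCGC 2 bp from the summit. That summit, at 15747550, lay beyond the 500 bp limit but near the 5' end of the CycE gene at 15748150. It lay at -451 bp from the TSS of an antisense RNA gene, CR44866.

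**Figure D4:**
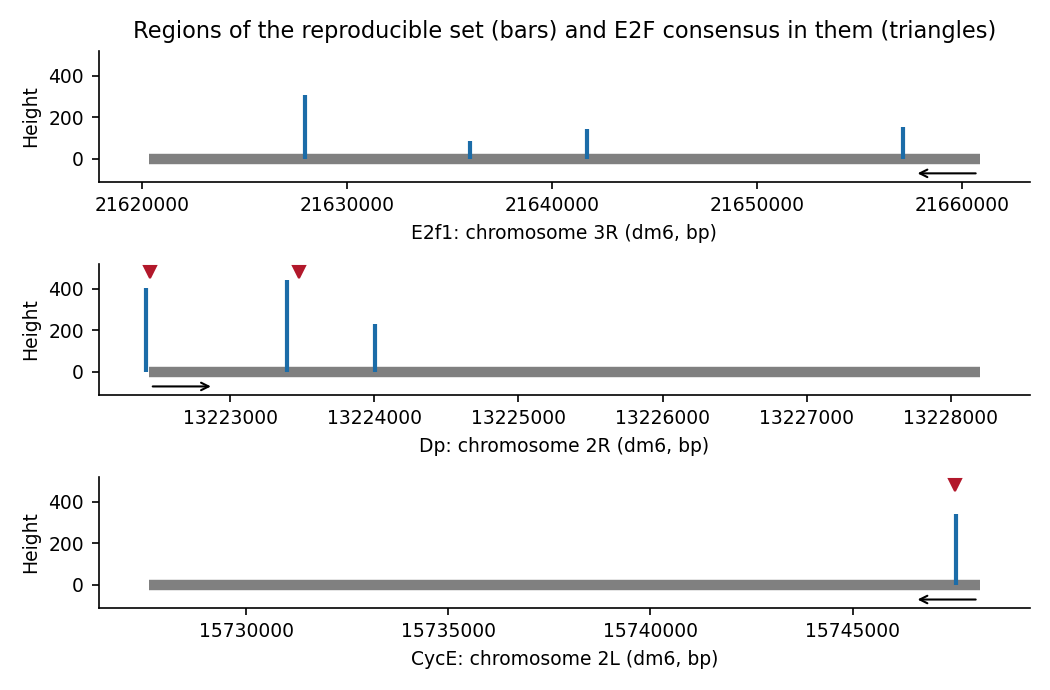
Height of each region of the reproducible set (vertical bars at the summits) along the E2f1, Dp and CycE genes (grey bars; arrows give the direction of transcription; horizontal axis in bp, dm6), with triangles at E2F consensus sites within the regions. E2f1 has 4 intronic regions without a site, and the CycE region of height 341 has a site 2 bp from its summit. The Dp regions of height 403 and 443 each have a site, and that of height 228 has none.

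By chromosome, genes on chromosome 4, the smallest, were bound at the lowest percentage. Of 80 coding genes on chromosome 4, 3 were bound (3.75%, exact 95% interval 0.780 to 10.6) against 17.7% elsewhere (odds ratio 0.181, exact adjusted p = 0.00190). There were 2 of 80 in replicate 1 (odds ratio 0.135, exact adjusted p = 0.00174) and 1 of 80 in replicate 2 (odds ratio 0.0783, adjusted p = 8.26e-04), and at an IDR of 0.001 the odds ratio was 0.0914 (adjusted p = 0.00478). Shares on the other arms ran from 16.3% on 2L to 19.2% on 3L, and none passed the test (exact adjusted p = 0.102 on 2L, 0.956 on 2R, 0.0609 on 3L, 0.395 on 3R and 0.395 on X). In each replicate alone the higher share on 3L did pass (odds ratios 1.14 and 1.22, exact adjusted p = 0.0438 and 0.00256), as did the lower share on X in replicate 1 (odds ratio 0.860, adjusted p = 0.0438). With a promoter distance of 1000 bp 2L (odds ratio 0.858, exact adjusted p = 0.0154) and 3L (1.14, adjusted p = 0.0213) passed. X passed at 200 bp (odds ratio 0.817, exact adjusted p = 0.0195). At an IDR of 0.001 X (0.803, exact adjusted p = 0.0104) and 3L (1.17, adjusted p = 0.0259) passed.

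By gene type, each of the 5 types tested against protein-coding genes was bound less often than their 17.6%. The number of TSSs per gene was not a covariate in these tests, and a gene with more TSSs can be called bound more easily. Of tRNA genes, which RNA polymerase III transcribes, 10 of 290 were bound (3.45%, odds ratio 0.167, exact adjusted p = 4.47e-13). Of snoRNA genes 4.46% were bound (exact adjusted p = 2.18e-10), of ncRNA genes 5.46% (178 of 3261, adjusted p = 5.08e-81) and of pseudogenes 1.12% (adjusted p = 5.92e-18). None of 99 rRNA genes was bound (exact 95% upper limit 3.66%, adjusted p = 1.05e-08), though reads from such repeated genes can be lost in mapping. With promoter distances of 200 and 1000 bp the odds ratios were 0.0741 and 0.300 for tRNA, 0.0531 and 0.672 for snoRNA (0.218 at 500 bp; exact adjusted p = 0.0219 at 1000 bp) and 0.174 and 0.433 for ncRNA genes (0.270 at 500 bp), and for pseudogenes 0.103 at 1000 bp (0.0529 at 500 bp).

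The sequence at the summits was AT-rich. Windows of 50 bp each side had a mean GC content of 33.8%, against 43.4% at 500 bp and 42.2% over the genome, and 78.2% of regions had a lower GC content at the summit than beside it. The E2F consensus was less frequent at summits than 500 bp away, 4.17% against 5.59% (ratio 0.746, adjusted p = 0.00377, exact McNemar test, two-sided, Benjamini-Hochberg over 8 motifs). This depended on the set: the ratio was 0.579 in replicate 2 (exact adjusted p = 3.06e-06) and 1.15 in replicate 1 (adjusted p = 0.195), and it was 1.13 over promoter summits only (adjusted p = 0.423). The call was lost at an IDR of 0.001 (ratio 0.768, exact adjusted p = 0.0578) and in the larger set (ratio 0.901, adjusted p = 0.264), and against dinucleotide-shuffled summit windows the ratio was 1.54 (adjusted p = 1.33e-04). The stricter form TTTSSCGC did not pass the test in the reproducible set (2.23% against 2.07%, exact adjusted p = 0.755) and was more frequent at summits in replicate 1 (ratio 1.55, adjusted p = 0.00388) and over promoter summits (ratio 1.83, adjusted p = 0.00613).

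The DRE, M1BP and CHR motifs were more frequent at summits than 500 bp away. Compared with windows 100 bp to either side this did not hold for M1BP, and for the DRE it held on 1 side only. With windows of 25 bp each side the M1BP ratio to windows 500 bp away was 10.5 (exact McNemar adjusted p = 5.09e-05). In 50 bp windows M1BP was at 0.473% at the summit and at 0.631% and 0.653% at 100 bp to either side. The DRE was at 0.811% at the summit and at 0.698% and 0.901% at 100 bp. The DRE (TATCGATA, the site of the factor DREF) was found at 1.71% of summits and 0.270% of control windows (ratio 6.33, exact adjusted p = 6.27e-12; 3.17 against windows 200 bp away and 17 over promoter summits), and the M1BP motif (GGTCACAC) at 0.991% and 0.248% (ratio 4.0, adjusted p = 1.11e-05). The CHR (TTYGAA, Y for C or T), a site of the dREAM complex in cell cycle promoters, was found at 20.7% and 12.5% (ratio 1.65, exact adjusted p = 2.78e-24). Against dinucleotide-shuffled summit windows the ratio was 1.18 for the CHR (17.5% of shuffled windows, exact adjusted p = 1.33e-04), 19 for the DRE (adjusted p = 2.21e-17) and 6.29 for M1BP (adjusted p = 2.29e-07). GAGA repeats were less frequent at summits (0.924% against 2.70%, ratio 0.342, exact adjusted p = 7.04e-10), with a ratio of 0.205 in replicate 2 alone (adjusted p = 5.78e-10), but not in replicate 1 alone (ratio 0.890, adjusted p = 0.510), and more frequent than in shuffled windows (ratio 1.86, adjusted p = 0.0218). The Zelda motif (0.496% against 0.473%, exact adjusted p = 1) and the initiator (8.65% against 9.17%, adjusted p = 0.555) did not pass the test in the reproducible set; the Zelda motif was less frequent over promoter summits (ratio 0.333, adjusted p = 0.0225) and the initiator in replicate 2 alone (ratio 0.792, adjusted p = 0.00571). In 5 equal groups by height, from the highest to the lowest, the E2F consensus was at 5.52%, 3.83%, 3.83%, 3.49% and 4.17% of summits. The DRE and M1BP calls were lost over summits outside promoters (ratios 1.60 and 1.67, exact adjusted p = 0.664 and 0.727), and the M1BP call also against windows 200 bp away (ratio 1.22, adjusted p = 0.533).

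**Figure D5:**
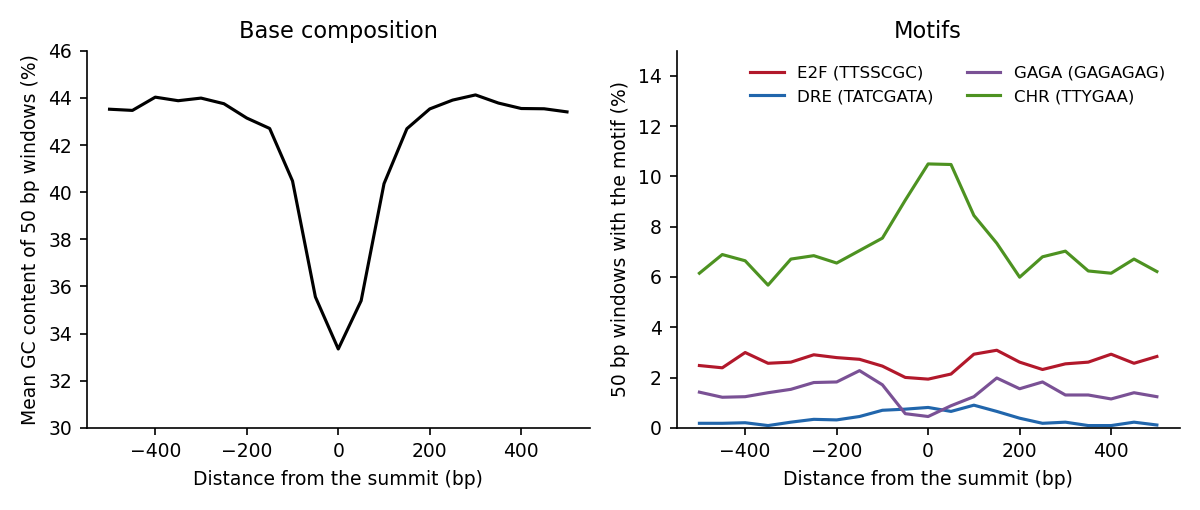
Left, mean GC content (%) of 50 bp windows by distance from the summit (bp) over the 4439 regions of the reproducible set; right, percent of those windows with each of 4 motifs. GC content falls to 33.3% at the summit, the CHR rises to 10.5%, and the E2F line dips to 1.94%.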

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

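Both values below were looked up after the sets had been seen, and neither was part of a planned comparison. Replicate 2 had 14 regions past the threshold on unplaced scaffolds of chromosome X, outside the sequence the comparisons use, and replicate 1 had 0. The highest of the 14 had a height of 161.

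Between the replicates 4542 regions passed the IDR threshold, and 103 of them were not in the reproducible set. Of these 61 lay on chromosome 3R and 28 on 2L, with median heights of 137 and 146, which is above the median of 113 in the reproducible set.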

How the results depend on the processing

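The settings of an IDR of 0.001, no shoulders (1 region per input region) and a q-like value of 0.05 were chosen after seeing the data. Values are odds ratios for arms, gene types and gene lists, ratios to control windows for motifs and percents for features and shared regions. Under other settings, with the calls on named genes counted apart in the last paragraph, 385 values kept their direction and side of the threshold, 18 passed it newly, 23 no longer did, 46 reversed and 6 without a test moved. The promoter, coding exon, 3' UTR and intergenic shares, chromosome 4, the gene types, the replication, ribosomal protein and chemoreceptor lists and the CHR kept their direction and side in every setting run, though not always their size. Of the reversed values, 4 passed the test in the new direction: the E2F consensus and GAGA against shuffled windows, Zelda over promoter summits and introns at 200 bp. The planned IDR of 0.01 is the authors' own threshold and removed nothing. Peak set and left-out replicate settings cannot apply to the shares of shared regions, and the covariate model could not be fitted for lists with 0 bound genes. No paired analysis was possible because the labels give a single group. Where no reason is given, the cause was not tested. With no read counts in the files, what depth limits is unknown.

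With each replicate left out in turn the ranges were 0.0783 to 0.135 for chromosome 4, 0.551 to 0.767 for the 3' UTR, 5.98 to 11.6 for replication, 6.64 to 7.37 for ribosomal proteins, 0.904 to 0.920 for 2R, 1.14 to 1.22 for 3L, 0.860 to 0.886 for X, 0.398 to 0.529 for the 5' UTR, 0.566 to 3.80 for E2F, Rb and dREAM components, 0.934 to 1.88 for cyclins, 3.46 to 9.60 for chromatin assembly, 0.958 to 1.93 for apoptosis, 0.846 to 1.21 for oxidative phosphorylation, 0.366 to 1.06 for muscle, 0.156 to 0.183 for patterning factors, 0.118 to 0.138 for testis, 0.579 to 1.15 for the E2F consensus, 0.831 to 1.55 for strict E2F, 0.205 to 0.890 for GAGA, 0.571 to 0.609 for Zelda and 0.792 to 0.904 for the initiator.

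An IDR of 0.001 left 2655 regions, which lowers the power of each test, and raised the shared part of replicate 1 to 75.6%. It gave 0.967 for 2R, 0.0914 for chromosome 4, 0.264 for coding exons, 10.2 for glycolysis, 1.17 for 3L, 0.803 for X, 0.452 for the 5' UTR, 2.68 for repair, 1.45 for E2F, Rb and dREAM components, 4.05 for chromatin assembly, 0.692 for cyclins, 0.830 for mitosis, 0.161 for testis, 0.768 for the E2F consensus, 0.750 for Zelda and 0.825 for the initiator. The larger set gave 0.969 for 2R, 0.775 for coding exons, 7.72 for repair, 7.34 for chromatin assembly, 0.650 for GAGA, 2.03 for E2F, Rb and dREAM components, 0.119 for patterning factors, 2.84 for mitosis, 0.901 for the E2F consensus and 0.786 for Zelda. In it the values were also further apart for gene list enrichment: DNA replication and nucleotide supply (9.91) and gene list enrichment: cytosolic ribosomal proteins (7.06). Without shoulders 2R was at 0.997, 3L at 1.14 and Zelda at 0.690. Wherever the set of summits changed, the sides of the control windows were drawn anew. Shifts of motif ratios between sets, that of Zelda among them, are therefore not effects of the setting alone. With a q-like value of 0.05 the values were 0.217 for coding exons, 0.975 for 2R, 1.07 for E2F, Rb and dREAM components, 1.04 for oxidative phosphorylation, 0.118 for testis and 0.714 for Zelda.

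A promoter distance of 200 bp gave 0.0741 for tRNA, 0.0531 for snoRNA and 0.174 for ncRNA genes, 0.946 for the 5' UTR, 0.766 for coding exons, 0.817 for X, 0.675 for cyclins, 0.0995 for patterning factors, 3.55 for glycolysis, 1.25 for oxidative phosphorylation, 0.157 for testis and 43.05% for introns, which then hold bases counted as promoter before. A distance of 1000 bp gave 0.300 for tRNA, 0.672 for snoRNA and 0.433 for ncRNA genes, 0.103 for pseudogenes, 0.0646 for chemoreceptors, 0.0901 for the 5' UTR, 0.248 for coding exons, 0.858 for 2L, 0.993 for 2R, 1.14 for 3L, 1.28 for E2F, Rb and dREAM components and 0.183 for testis. With 1 gene per TSS cluster the values were 1.11 for E2F, Rb and dREAM components, 1.04 for neuronal genes, 1.29 for oxidative phosphorylation and 0.129 for testis. Against genes with a candidate region they were 3.23 for chromatin assembly, 0.221 for patterning factors and 0.119 for testis, and by overlap of the whole region 1.44 for E2F, Rb and dREAM components and 0.0960 for testis. With covariates cyclins were at 0.955 and glycolysis at 3.42.

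For motifs, control windows 200 bp away gave 3.17 for the DRE, 1.22 for M1BP, 0.786 for Zelda and 0.908 for strict E2F. Shuffled windows gave 1.18 for the CHR, 19 for the DRE, 6.29 for M1BP, 1.54 for the E2F consensus, 1.86 for GAGA, 1.04 for the initiator and 1.98 for strict E2F. Summits outside promoters gave 1.60 for the DRE, 1.67 for M1BP and 0.686 for strict E2F, and promoter summits 17 for the DRE, 1.13 for the E2F consensus, 0.333 for Zelda, 1.05 for the initiator and 1.83 for strict E2F. Windows of 100 bp each side gave 0.870 for Zelda and of 25 bp each side 1.00 for strict E2F and 10.5 for M1BP. Shared parts fell to 58.1% of replicate 1 and 66.4% of replicate 2 with a reciprocal overlap of 50%, as a stricter form of the same rule must. With summits within 100 bp they were 63.1% and 72.7%.

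For the 62 named genes 584 calls in other settings were kept, 18 were gained and 18 lost. Of these genes, 10 were no longer bound with a distance of 200 bp, and 7 more were bound and 1 fewer with the larger set. Leaving out replicate 2 added 5 and removed 1, and leaving out replicate 1 added 1 and removed 3.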

Other observations

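The tests on the added gene families, on low regions, on motifs at the summits of single lists, on tRNA genes and on regions or genes of 1 replicate alone were chosen after the results had been seen. The last of these replaced an earlier comparison of peak heights between the replicates, which was set aside because heights from separately called lists share no known scale. Outside the fixed lists, 3 families were bound less often than other genes: cuticle proteins (1 of 110, odds ratio 0.0424, adjusted p = 1.21e-07, Fisher's exact test over 6 families), odorant-binding proteins (1 of 51, odds ratio 0.0930, adjusted p = 0.00383) and cytochromes P450 (5 of 83, odds ratio 0.298, adjusted p = 0.00690). In replicate 1 and replicate 2 the bound shares were 0.909% and 0 for cuticle proteins, 1.96% in both for odorant-binding proteins, and 2.41% and 3.61% for cytochromes P450 against 6.02% in the reproducible set. Mitochondrial ribosomal protein genes, which include mRpL41, were bound in 20 of 73 cases (27.4%, odds ratio 1.77, exact adjusted p = 0.0651), against 58.7% for the cytosolic ones. Aminoacyl-tRNA synthetases (7 of 32, exact adjusted p = 0.587) and proteasome subunits (8 of 48, adjusted p = 1) did not pass the test. In the reproducible set 124 regions had a height under 20, and 123 of them (99.2%) were matched to the same input region as a higher neighbour, against 1.16% of the other regions.

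The E2F consensus was more frequent at promoter summits of replication genes than at other promoter summits. It lay at 11 of 27 promoter summits of the replication list (40.7%) against 5.36% of the other promoter summits (odds ratio 12.1, adjusted p = 2.27e-07, Fisher's exact test over 9 comparisons), and at 4 of 56 summits of ribosomal protein genes (7.14%, adjusted p = 0.566). The DRE lay at 6 of the 27 (22.2%, odds ratio 8.48, exact adjusted p = 3.79e-04) and at 14 of the 56 (25%, odds ratio 11.2, adjusted p = 1.91e-08).

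Over all summits the E2F consensus was not more frequent than 500 bp away. With 100 bp each side the ratio was 0.786, so widening the window to that size gave no excess over the control windows. That window keeps the AT-rich centre and does not reach sites farther out, such as those at RnrS, ph-p and Tcs5 (119, 124 and 156 bp from the summit). It cannot decide on such sites. The AT-rich composition of the summits may hide an enrichment, as the ratio to dinucleotide-shuffled summit windows was 1.54. An excess of sites limited to replication, repair and chromatin assembly promoters may also be part of it and stays open. Summits of these lists carried the consensus more often than the other promoter summits (14 of 50 against 99 of 1880, odds ratio 6.996, Fisher's exact p = 3.96e-07). The 99 sites elsewhere did not pass the test against the 122 in control windows (ratio 0.811, exact McNemar p = 0.126). That comparison cannot tell whether the excess is limited to these lists. The sides of its control windows were drawn anew, and over all promoter summits, in another draw, the ratio was 1.13. Of the 14 summits in these lists with the consensus, 11 were among the 27 summits of replication genes. The repair and chromatin assembly lists were not tested apart. Dilution by weak regions cannot be told apart from chance, because the fifth of regions with the highest peaks gave a ratio of 0.942 with an exact p = 0.838; with 1 group, no biological explanation was tested.

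In the reproducible set ribosomal protein promoters were bound at a percentage near that of replication promoters, 58.7% and 58.5%, but in replicate 1 at a lower one, 57.6% and 68.3% (odds ratios 7.37 and 11.6), and in replicate 2 at 51.1% and 48.8%; the difference was not tested. Signal that follows heavy transcription by any polymerase is argued against by tRNA genes, with an odds ratio of 0.167 (0.0741 and 0.300 with promoter distances of 200 and 1000 bp). Of the 275 tRNA genes with at least 80% of the 50 bp stretches around them unique in the genome, 3.64% were bound. This prediction was written after the tRNA result had been seen. The odds ratios of tRNA genes were not adjusted for the number of TSSs per gene. No transcription level was measured, and tRNA genes, which RNA polymerase III transcribes, do not speak to genes of RNA polymerase II. Of the highest summits at the bound ribosomal protein genes, 11.1% (6 of 54, exact 95% interval 4.19 to 22.6) lay downstream of the TSS. This argues against promoter signal centred downstream of the TSS. Since these summits were picked within 500 bp of a TSS, and a summit gives no spread, signal over the rest of the gene bodies was not tested. Promoter base composition and TSS number as the whole cause are argued against by an odds ratio of 5.48 with these as covariates. Signal tied to RNA polymerase II promoters in particular was not tested, and no control precipitation was used here, so E2f1 binding at these promoters is a hypothesis.

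Regions in the set of replicate 1 alone carried the E2F consensus more often than regions in the set of replicate 2 alone, 120 of 1228 (9.77%) against 18 of 808 (2.23%; odds ratio 4.75, adjusted p = 1.58e-11, Fisher's exact test over 8 motifs). They also carried the DRE (odds ratio 4.16), M1BP (9.06) and GAGA (5.47) motifs more often and the CHR less often (16.6% against 21.2%, odds ratio 0.742, exact adjusted p = 0.0135), and had a GC content of 40.3% against 33.8%. With GC content as a covariate the odds ratio was 2.85 (95% interval 1.70 to 4.78), with sets of equal size 5.19 and over promoter summits 8.74, which argues against each of these as the whole cause, though GC content may be part of it. Replication genes bound in 1 replicate alone were Cdc6, Mcm10, Mcm3, Orc3, PolA2, Psf2, RnrL, Sld5 and Ts in replicate 1 and RPA1 in replicate 2, a split that did not pass the test against that of the other genes (9 to 1 against 613 to 342, odds ratio 5.02, adjusted p = 0.536, Fisher's exact test over 5 lists). A difference between the embryo collections stays open and untested, as the labels give nothing on the replicates beyond their number.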
